A study of Mus musculus with 18 samples.

How the data were processed

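The series holds RNA sequencing of lipochondrocytes from mouse ear cartilage at P8, P10, P13, P21 and P33 and of adipocytes from inguinal fat at P33, with 3 libraries per group and 18 in all. Per the labels, P8, P10 and P13 cells came from Wnt1-Cre2;TdTomato mice, were released with collagenase and were sorted for high TdTomato. P21 and P33 lipochondrocytes and the adipocytes were collected as the buoyant fraction after centrifugation. The labels number the libraries 1 to 3 in each group and do not say whether each was a separate animal or a pool.

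The deposited expression table holds FPKM (fragments per kilobase of gene, relative to the mapped fragments of the library) as calculated by the authors, with 1 column per library and 2 decimals. Per the submitters' processing notes, reads were aligned with STAR 2.4.2a to mm10. The quantifier and the gene annotation are not given in the sources used here. A second deposited table gives, per the file headers, a count of total reads and of paired reads for each library, and the percent of reads paired and the alignment rate in percent. It is not stated whether total reads are single reads or pairs, or whether the alignment rate covers unique alignments only. Totals ran from 12461965 to 27640142 per library and alignment rates from 73.19% to 84.44%, and 100% of reads were paired. The sorted libraries had alignment rates of 77.44% to 84.44% and the P21 and P33 libraries 73.19% to 79.37%. FPKM carry no counts per gene, so no counting intervals are given, and a value listed at 0 is not shown to be absent. The columns sum to 880622 to 1245105 FPKM. Between 9254 and 11748 genes reached 1 FPKM, with 9254 to 10558 in the sorted, 10759 to 11610 in the P21 and P33 and 11672 to 11748 in the adipocyte libraries. The 20 most abundant genes of a library took 35.1% to 51.4% of its FPKM. No 2 libraries held identical values (0 found), and 0 of the per-sample columns were left unused.

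The table lists 46983 genes by Ensembl identifier and symbol, of which 18837 are listed at 0 in all libraries. Ignoring the version suffix, 98.9% of identifiers are in GENCODE M21 (GRCm38, mm10), from which coordinates were taken. Symbols are as the table gives them; of 418 members of the gene lists, 412 matched by current symbol, 5 by an older symbol and 1 by gene identifier.

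FPKM were changed to log2(FPKM + 1), with a pseudocount of 1, and genes with at least 1 FPKM in at least 3 of the 18 libraries were kept, which left 13815. A linear model with 6 group means was fitted to all 18 libraries with limma 3.58.1 in R 4.3.3, using moderated statistics with a mean-variance trend. Each of 11 comparisons was tested two-sided, with p adjusted by Benjamini-Hochberg over genes within the comparison, and genes with adjusted p below 0.05 are called. The median standard error was 0.170 on the log2 scale. The 4 main comparisons were P33 with adipocytes, P13 with P8, P21 with P13 and P33 with P21. Adipocytes and P33 match in age and isolation, while P21 and P13 differ in both. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

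In all, 30 gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 30 lists within each comparison, and again with a correlation estimated for each list. The lists were cartilage matrix, chondrocyte transcription factors, elastic fibre, hypertrophy and mineralization, collagen processing, fatty acid synthesis, triglyceride synthesis, lipid droplet coat, lipolysis, fatty acid uptake, fatty acid oxidation, adipocyte identity, brown fat, cholesterol synthesis, glycolysis, oxidative phosphorylation, proliferation and the dissociation response, and markers of skeletal muscle, keratinocytes, sebocytes, endothelium, macrophages, lymphocytes, fibroblasts and perichondrium, smooth muscle and pericytes, Schwann cells, melanocytes, erythroid cells and mammary epithelium. Counts of called members are given over all genes and adjusted over the list alone. List sizes in the results count only members that passed the FPKM filter. These were 9 of 12 transcription factors, 6 of 15 hypertrophy, 8 of 13 skeletal muscle, 3 of 12 keratinocyte, 1 of 8 sebocyte, 3 of 10 lymphocyte and 2 of 9 Schwann cell genes. A member could pass through the adipocyte libraries alone, which favours lower calls in lipochondrocytes for such members. The comparisons, tests, lists, the rule for naming genes and the alternatives below, unless stated, were chosen before the data were examined.

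Genes were named by a rule: in each main comparison, the 6 largest rises and 6 largest falls among called genes whose groups did not overlap, which chance gives in 10% of genes for 3 libraries against 3, with a mean of at least 10 FPKM in the higher group and a standard symbol; up to 3 called members per list with the largest change; and 26 genes of interest. The rule took 101, 67, 99 and 83 genes in the 4 main comparisons, from which the text gives a part. It also took Rps3a2 and Rps3a3, which GENCODE M21 lists as processed pseudogenes; these are given under other observations only. Outside the rule, and after their values were seen, members that moved against their list or made up a short count, the course of 1520401A03Rik, Apoe, Sparc and Gsn, and genes with an opposite course in the early and late stages were named. Y-linked genes and Xist were left out.

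The workflow was tested on simulated data with the same number of libraries and the same group labels. In the P33 to adipocyte comparison it recovered 81 of 100 genes moved 2-fold and 95 of 100 moved 4-fold, with 10 false calls (5.38% of calls). For P13 with P8 the numbers were 74, 92 and 6 (3.49%), for P21 with P13 they were 76, 96 and 11 (6.01%), and for P33 with P21 they were 71, 95 and 17 (9.29%). The moved list was found in each of these 4 comparisons, and 0 of 30 unmoved lists were called. Simulated genes were drawn independently of each other, and moved genes only from the more abundant ones. Apart from the moved genes, all groups shared the same mean and the same spread for each gene, with no shift over all genes. The simulation therefore cannot show how list tests behave where the genes of a list are correlated. Nor can it show how calls behave where groups differ in spread or most genes shift.

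Alternatives were a pseudocount of 0.1, no filter, a minimum of 5 FPKM, median-of-ratios scaling, rescaling each library to the same sum, quantile normalization, a model of only the 2 groups compared, sample weights, a minimum of 2-fold, a block for the replicate number and leaving out each library of a comparison in turn. Leaving out the 20 genes with the highest mean FPKM, and the test for an opposite course, were chosen after seeing the data. All splits of the 6 libraries of each comparison into 3 and 3 were also tested.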

Results

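Lipochondrocytes, the lipid-storing cells of mouse ear cartilage, were profiled by RNA sequencing at postnatal days 8, 10, 13, 21 and 33 (P8 to P33), beside adipocytes from inguinal fat of P33 mice, with 3 libraries in each of the 6 groups. The 15 lipochondrocyte libraries carried cartilage transcripts at every stage, and Col2a1, Eln and Cytl1 were each far above the adipocyte level. Cells of P8, P10 and P13 had been sorted for TdTomato, whereas P21 and P33 lipochondrocytes and the adipocytes had been collected as a buoyant fraction. On the first principal component (57.9% of the variance) the adipocyte libraries lay at 169.55 to 170.44 and the lipochondrocyte libraries at -57.60 to -5.89. The second component (20.1%) placed the 9 sorted libraries at -50.29 to -24.02 the P21 and P33 libraries at 56.97 to 68.15 and the adipocyte libraries, buoyant as well, at -23.88 to -22.46, next to the sorted ones. Mitochondrial genes took 23.3% to 25.5% of the FPKM (fragments per kilobase of gene, relative to library size) in adipocytes and 3.7% to 6% in lipochondrocytes. The labels do not say that replicates were separate animals, so p-values here measure the spread between these libraries. Values below are mean ± SD (SD, n = 3) in FPKM, and changes are on the log2(FPKM + 1) scale with their standard error (SE).

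**Figure D1:**
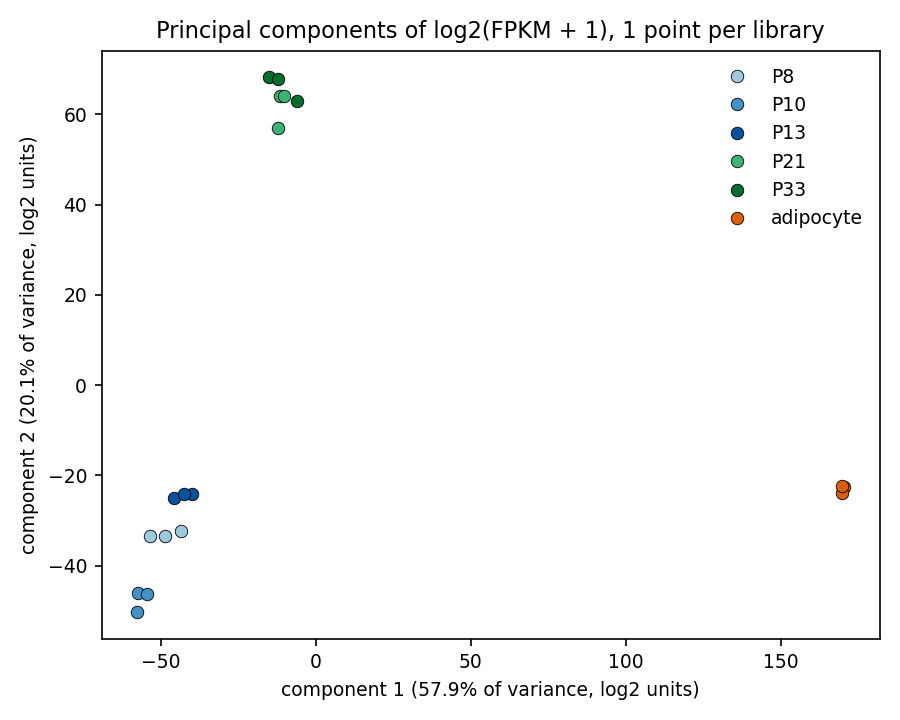
Scores of the 18 libraries on the first 2 principal components of log2(FPKM + 1), 1 point per library and 1 colour per group, with the percent of variance on each axis. The adipocyte libraries lie at 169.55 to 170.44 on the first component, and the second component separates the sorted from the buoyant lipochondrocyte libraries but places the buoyant adipocytes near the sorted ones.

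At P33, the age at which both cell types had been collected as a buoyant fraction, lipochondrocytes and adipocytes shared high levels of a few lipid genes and differed in most others. Dgat2, the last enzyme of triglyceride synthesis, stood at 1190 ± 390 FPKM in lipochondrocytes and 1850 ± 48 in adipocytes, and the desaturase Scd1 at 2800 ± 1200 and 10200 ± 550. The droplet coat gene Plin2 was at 269 ± 53 against 613 ± 20. In contrast, the adipocyte genes Adipoq, Cfd, Fabp4 and Cidec were near 0 in lipochondrocytes, and the cartilage genes Cytl1, Mia and Col2a1 were near 0 in adipocytes. Cytl1 (ENSMUSG00000062329.4, chromosome 5:37735519 to 37739820 of GRCm38) was the gene furthest above adipocytes, at 18500 ± 2200 against 0.99 ± 0.46 FPKM (log2 difference 13.21, SE 0.20, adjusted p = 7.26e-17). Angptl7 reached 2720 ± 880 against 0.0867 ± 0.072 (11.24, SE 0.35, adjusted p = 2.94e-13), and Col8a1 reached 5180 ± 460 against 1.58 ± 0.071. Chad (2250 ± 1000) and Acan (98.4 ± 41) were listed at 0 in all adipocyte libraries. Col2a1 (ENSMUSG00000022483.16, chromosome 15:97975602 to 98004695) was higher by 7.78 (SE 0.17, adjusted p = 3.87e-15), Eln (ENSMUSG00000029675.12, chromosome 5:134702593 to 134747323) by 8.85 (SE 0.25, adjusted p = 8.44e-14), and Sox9 by 6.03 (SE 0.22, adjusted p = 1.85e-12).

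Cfd (ENSMUSG00000061780.5, chromosome 10:79890853 to 79892655) was the gene furthest below adipocytes, at 0.553 ± 0.27 in lipochondrocytes against 37300 ± 3200 FPKM (log2 difference -14.56, SE 0.16, adjusted p = 4.28e-18). Adipoq (ENSMUSG00000022878.5, chromosome 16:23146536 to 23158028) was at 0.543 ± 0.66 against 7700 ± 250 (-12.36, SE 0.19, adjusted p = 1.11e-16). Fabp4 (ENSMUSG00000062515.3, chromosome 3:10204088 to 10208576) was at 4.73 ± 0.93 against 33500 ± 1200 (-12.53, SE 0.17, adjusted p = 2.53e-17). The droplet genes Cidec (ENSMUSG00000030278.11, chromosome 6:113424634 to 113435760) and Plin1 were lower by -11.32 and -8.16, and Lpl by -10.15. Lep, Adrb3, Ucp1 and mt-Tq were listed at 0 in every P33 lipochondrocyte library, against 176 ± 1.6 for Lep, 192 ± 4.8 for Adrb3 and 36.7 ± 0.38 for Ucp1 in adipocytes. The lipid genes present in both cells differed less. Scd1 (ENSMUSG00000037071.2, chromosome 19:44394455 to 44407879) was lower by -1.97 (SE 0.27, adjusted p = 8.94e-06), Plin2 (ENSMUSG00000028494.12, chromosome 4:86648386 to 86670060) by -1.21 (SE 0.14, adjusted p = 1.29e-06) and Fasn by -3.90 (SE 0.21, adjusted p = 2.07e-10). Dgat2 (ENSMUSG00000030747.4, chromosome 7:99153658 to 99182719) was lower by -0.68 (SE 0.19, adjusted p = 4.35e-03), but by -0.33 and no longer called under median-of-ratios scaling (adjusted p = 1.11e-01).

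Of the 13815 genes tested, 9466 differed between P33 lipochondrocytes and adipocytes, 3315 higher and 6151 lower in lipochondrocytes. The median difference over all genes was -0.280. Under median-of-ratios scaling of the libraries it was -0.017, and the split became 4188 higher and 4825 lower. Gene list counts adjusted over the list alone equalled those over all genes for all 30 lists in this comparison. Of 21 cartilage matrix genes, 20 were higher and only Epyc was not called (list test adjusted p = 6.59e-17, and 8.07e-04 with an estimated correlation). All 16 adipocyte identity genes, among them Cfd, Adipoq and Retn, were lower (3.54e-10, and 0.00766 with an estimated correlation), as were all 17 fatty acid oxidation genes such as Hadhb and Acadm (1.51e-07, and 0.0416). Of the droplet coat list, 10 of 12 were lower and Cideb was higher (0.00162, and 0.0455 with an estimated correlation). Of 12 lipolysis genes, 10 were lower, led by Adrb3, Lipe and Pnpla2, while 2 were higher, among them G0s2 (2.21) (0.00117, and 0.0453). Fatty acid uptake had 12 of 15 lower, led by Cd36 and Lpl, with Lrp1 and Slc27a3 higher (0.00162, and 0.0455). These counts under median-of-ratios scaling were 20 higher for cartilage matrix, 16 lower for adipocyte identity, 17 lower for oxidation, 9 lower for droplet coat, 10 lower for lipolysis and 11 lower for uptake.

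Several other lists of this comparison passed only with the preset correlation. Fatty acid synthesis had 13 of 17 lower, led by Thrsp, Me1 and Acly, and 3 higher, which were Fads2, Acsl3 and Srebf1 (adjusted p = 0.00335, and adjusted p = 0.343 with an estimated correlation). Triglyceride synthesis had 12 of 14 lower, among them Gpd1 and Agpat9, and Lpin2 higher (0.00162, and 0.138 with an estimated correlation). Oxidative phosphorylation had 18 of 20 lower, led by Uqcrfs1 and Ndufs1 (1.21e-05, and 0.163). Brown fat genes had 7 of 10 lower and 2 higher (0.0402, and 0.0993). Elastic fibre genes had 12 of 16 higher, led by Eln, Mfap4 and Mfap2, with Fbln1 and Efemp1 lower (6.78e-05, and 0.0857). Collagen processing had 8 of 18 higher, led by Fkbp10 and Pcolce, and 3 lower (0.00335, and 0.244). Of 9 chondrocyte transcription factors, Sox9, Sox5, Sox6 and Barx1 were higher while Creb5 and Runx1 were lower (0.0471, and 0.277). Fibroblast and perichondrium genes had 9 of 14 higher, led by Col1a2, Col1a1 and Tnmd, and 2 lower (3.22e-04, and 0.163). Cholesterol synthesis (2 higher, 11 lower of 20, adjusted p = 0.22), glycolysis (4 and 11 of 20, 0.503), proliferation (1 and 7 of 22, 0.968) and hypertrophy (3 and 2 of 6, 0.103) were not called as lists. Under median-of-ratios scaling the higher and lower counts were 3 and 12 for fatty acid synthesis, 2 and 11 for triglyceride synthesis, 0 and 18 for oxidative phosphorylation, 2 and 7 for brown fat, 12 and 1 for elastic fibre and 12 and 2 for collagen processing. They were 5 and 1 for the transcription factors, 10 and 1 for fibroblast genes, 2 and 10 for cholesterol synthesis, 5 and 8 for glycolysis, 3 and 3 for proliferation and 4 and 2 for hypertrophy.

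Markers of other cell types also separated these preparations. All 12 endothelial genes, such as Gpihbp1, Cldn5 and Esam, were lower in lipochondrocytes (adjusted p = 7.46e-06, and 0.0416 with an estimated correlation), and so were all 12 macrophage genes, such as Lyz2 (24 ± 8.2 against 471 ± 21 FPKM; list 8.57e-06, and 0.0416). The 3 lymphocyte genes that passed the filter, of 10 listed, were lower (0.0201, and 0.105 with an estimated correlation). So were the 5 erythroid genes that passed, of 7 listed (0.0424, and 0.312). Of 8 skeletal muscle genes, 7 were higher, among them Tnni2 at 19 ± 20 against 0.16 ± 0.14 FPKM (0.0111, and 0.404 with an estimated correlation). The dissociation response, a list of immediate early and heat shock genes, had 15 of 16 lower in lipochondrocytes, with Fos at 1.7 ± 0.49 against 1710 ± 58 FPKM (4.43e-07, and 0.0857). Not called as lists were keratinocyte (2 of 3 genes higher, 0.0595), sebocyte (Krt79 lower, 0.12), smooth muscle and pericyte (1 higher and 3 lower of 6, 0.503), Schwann cell (1 higher and 1 lower of 2, 0.872), melanocyte (1 gene, not called, 0.776) and mammary epithelium (Krt8 higher and Krt19 lower, 0.696).

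The younger stages differed from adipocytes by similar numbers of genes. The calls numbered 9331 at P21 (3379 higher, 5952 lower), 9924 at P13 (2462 higher, 7462 lower), 10463 at P10 (2326 higher, 8137 lower) and 9879 at P8 (2668 higher, 7211 lower). The all-gene medians were -0.252, -0.557, -0.733 and -0.512, and moved to -0.022, -0.030, -0.035 and -0.020 under median-of-ratios scaling. The splits were then 4105 higher and 4768 lower at P21, 4148 and 4797 at P13, 4414 and 5103 at P10, and 4242 and 4977 at P8. At P13, P10 and P8 the isolation and the age differed from those of the adipocytes as well as the cell type.

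From P8 to P13, both sorted, the lipid genes Scd1, Dgat2, Plin2, G0s2 and Cidea rose, while Col2a1, Eln and Sox9 were not called. Scd1 rose from 31.1 ± 6.3 to 223 ± 21 FPKM, Dgat2 from 127 ± 9.7 to 476 ± 54, and Plin2 from 17.8 ± 0.21 to 62.6 ± 6.7. G0s2, an inhibitor of lipolysis, rose from 221 ± 43 to 892 ± 91, and Cidea from 4.95 ± 0.8 to 18.1 ± 1.8. Adipoq was at 0.05 ± 0.087 FPKM at P13 and Fabp4 at 1.83 ± 0.35, and neither was called. The changes were 2.81 for Scd1 (SE 0.27, adjusted p = 1.65e-05), 1.89 for Dgat2 (SE 0.19, adjusted p = 2.20e-05), 1.75 for Plin2 (SE 0.14, adjusted p = 3.22e-06), 2.02 for G0s2 (SE 0.17, adjusted p = 6.21e-06) and 1.69 for Cidea (SE 0.16, adjusted p = 1.98e-05). Mogat1 rose by 1.81 (adjusted p = 2.29e-03). Fasn rose by 0.88 (SE 0.21, adjusted p = 2.65e-02) and lost its call under 4 of the alternatives and without each of P8 replicates 1 and 2 and P13 replicates 1, 2 and 3. Osgin1, Omd, Cbr2, Clu and Spp1 were among the 6 largest rises beside Scd1, with Omd going from 7.21 ± 1.5 to 56.2 ± 7 FPKM and Spp1 from 1.16 ± 0.26 to 11.2 ± 1.6. Among the falls were Dlk1 (-2.32, lost with only these 2 groups modelled at 1.52e-01), Sfrp2 (-1.92, SE 0.19, adjusted p = 2.59e-05), H19 (-1.65) and Tgfbi (-1.63). Col2a1 (5100 ± 1300 and 4250 ± 490 FPKM, adjusted p = 5.42e-01), Eln (28100 ± 5100 and 24200 ± 880, adjusted p = 7.76e-01) and Sox9 (209 ± 28 and 239 ± 50, adjusted p = 7.76e-01) were not called.

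In all, 581 genes changed from P8 to P13, with 371 rises and 210 falls, against 381 without P8 replicate 1, 339 without P13 replicate 3 and 347 with only these 2 groups modelled. Rises numbered 246 without P13 replicate 2, and falls 128 without P8 replicate 3 and 119 without P13 replicate 1. Of 17 fatty acid synthesis genes, Scd1, Fasn and Slc25a1 rose and none fell, or 5 adjusted over the list alone (list test adjusted p = 3.90e-07, but adjusted p = 0.267 with an estimated correlation). Triglyceride synthesis had 3 rises of 14 (Dgat2, Mogat1 and Gpd1), or 4 rises and 1 fall over the list alone (0.00319, and 0.267 with an estimated correlation). Droplet coat had 2 of 12 (Plin2 and Cidea), or 4 over the list alone (1.36e-04, and 0.0897), and oxidation had 3 of 17 (Etfb, Etfa and Slc25a20), or 5 (0.00218, and 0.267). Cartilage matrix had 5 rises of 21, which were Snorc (listed under an older symbol), Col11a1, Col9a1, Mia and Epyc, or 6 over the list alone (4.85e-04, and 0.138). Among elastic fibre genes Efemp2 rose while Fbln2, Ltbp2, Mfap4 and Fbln5 fell, or 3 rises and 7 falls over the list alone (0.0248, and 0.468). The Ltbp2 call was lost with only these 2 groups modelled (adjusted p = 6.08e-02). Cholesterol synthesis (1 rise, or 3 over the list alone, 0.00535, and 0.514 with an estimated correlation) and oxidative phosphorylation (1 rise, 0.0138, and 0.514) moved up as lists with few single genes called. Proliferation genes moved down as a list (5.89e-05, and 0.138), with Ccna2 and Mcm6 called, or 3 genes over the list alone. The calls of Gpd1, Etfb, Etfa, Slc25a20, Col11a1, Col9a1, Mia, Mfap4, Ccna2 and Mcm6 were each lost without P13 replicate 3 (adjusted p from 6.19e-02 to 1.35e-01) and without at least 1 other library, which was P8 replicate 1 for all but Etfa and Mcm6 and P8 replicate 3 for those. The dissociation response changed between these stages as well: Btg2 (2.41), Atf3 (1.73), Fosb (1.43) and 4 others rose while Hspa1a and Hspa1b fell, or 9 rises and 3 falls over the list alone (5.89e-05, and 0.267). The Fosb call was lost with a pseudocount of 0.1 (adjusted p = 5.30e-02). Among fibroblast genes Ly6a rose while Col1a1, Postn and Col14a1 fell, or 2 rises and 4 falls over the list alone, and the list was not called (0.0731). Skeletal muscle (0.0138, and 0.514) and smooth muscle (0.0261, and 0.267) lists moved with 0 genes called. No list of this comparison held with an estimated correlation.

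The P10 libraries lay apart from both neighbours in fibroblast and perichondrium genes, and other lists moved with them. From P8 to P10, 5 of these 14 genes rose, or 11 adjusted over the list alone (list test adjusted p = 3.81e-17, and 0.0358 with an estimated correlation), and from P10 to P13, 12 of the 14 fell (7.37e-16, and 0.0478). Ly6a went from 4.04 ± 0.84 at P8 to 21 ± 0.4 at P10 and 7.08 ± 0.87 at P13, and Col14a1 from 16.2 ± 2.2 to 20.4 ± 1.7 and 6.64 ± 0.63. From P8 to P10 the dissociation response had 6 rises and 2 falls (5.68e-08, and 0.141 with an estimated correlation), and the macrophage (4.60e-06, and 0.0608) and Schwann cell (0.00114, and 0.121) lists moved up as well, with 0 and 1 genes called. Both moved back down from P10 to P13 (0.0115, and 0.256 for macrophage; 0.00479, and 0.163 for Schwann cell). Elastic fibre genes likewise moved up with 2 rises (5.47e-04, and 0.241) and then down with 6 falls and 1 rise (2.12e-06, and 0.138). Skeletal muscle (0.00582, and 0.692) and cholesterol synthesis (0.015, and 0.692) moved up from P8 to P10 with 0 genes called, and proliferation (1 fall, 0.00212, and 0.208) and collagen processing (4 falls and 2 rises, 0.0188, and 0.569) moved down from P10 to P13. The lipid genes Scd1 (35.4 ± 1.7 FPKM at P10), Dgat2 (96.4 ± 11) and Plin2 (14 ± 0.75) showed their rise between P10 and P13. Of 17 oxidation genes, 6 fell from P8 to P10, or 8 over the list alone (0.00437, and 0.401), and 11 rose from P10 to P13, or 12 over the list alone (1.18e-04, and 0.163 with an estimated correlation), and from P10 to P13 so did 7 of 17 fatty acid synthesis genes, or 8 (0.00212, and 0.569), and 5 of 12 droplet coat genes, or 7 (0.0043, and 0.138). Counts were 1525 genes for P10 against P8 (262 higher, 1263 lower) and 3124 for P13 against P10 (2567 higher, 557 lower). The first count was 640 without P8 replicate 2, 914 without P8 replicate 3, 520 without P10 replicate 1, 794 without P10 replicate 2 and 351 with only these 2 groups modelled (161 higher, 190 lower), and the second was 1938 without P10 replicate 1, with 1657 rises and 426 falls without P13 replicate 2. Median-of-ratios scaling moved the all-gene medians from -0.190 to 0.003 and from 0.149 to 0.000, and turned the splits to 497 higher and 125 lower, and to 1125 and 1183. After that scaling 0 oxidation genes fell from P8 to P10, while the dissociation response had 8 rises and 1 fall, fibroblast genes 10 rises, elastic fibre 3 rises and cholesterol synthesis 3 rises. From P10 to P13 there were then 8 rises for oxidation, 6 for fatty acid synthesis and 4 for droplet coat, against falls of 13 fibroblast, 9 elastic fibre (with 1 rise), 9 collagen processing and 8 proliferation genes.

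Between P13 and P21 Scd1, Dgat2 and Plin2 rose further, the immediate early genes fell to a small part of their level, and the matrix genes went in both directions. Scd1 went from 223 ± 21 to 5110 ± 1100 FPKM, Dgat2 from 476 ± 54 to 4470 ± 660 and Plin2 from 62.6 ± 6.7 to 699 ± 110. Cilp2, Comp and Angptl7, each under 5 FPKM at P13, were above 200 at P21, while Col2a1 and Eln fell. Fos fell from 10700 ± 730 to 16.7 ± 17 FPKM. The isolation changed from sorting to buoyancy between these stages, so stage and isolation cannot be separated here. Changes were 4.50 for Scd1 (SE 0.27, adjusted p = 8.71e-09), 3.22 for Dgat2 (SE 0.19, adjusted p = 7.00e-09), 3.45 for Plin2 (SE 0.14, adjusted p = 1.26e-10), 2.70 for Fasn (adjusted p = 1.68e-07), 3.44 for Slc25a1 (adjusted p = 4.91e-11) and 2.30 for G0s2 (adjusted p = 1.03e-07). Fabp4 rose by 2.62 to 16.4 ± 2.9 FPKM. Adipoq reached 0.563 ± 0.025 FPKM (adjusted p = 2.43e-02) and Plin1 0.677 ± 0.37 (adjusted p = 2.62e-02), and both calls were lost under median-of-ratios scaling (5.59e-02 and 1.09e-01), without P13 replicate 2 (6.59e-02 and 1.09e-01) and without P21 replicate 3 (5.36e-02 and 1.33e-01). Lpl (-0.06, adjusted p = 7.54e-01) and Pparg (0.26, adjusted p = 3.29e-01) were not called, except Lpl under median-of-ratios scaling (3.47e-02) and quantile normalization (1.92e-02) and Pparg without P21 replicate 3 (4.89e-02).

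**Figure D2:**
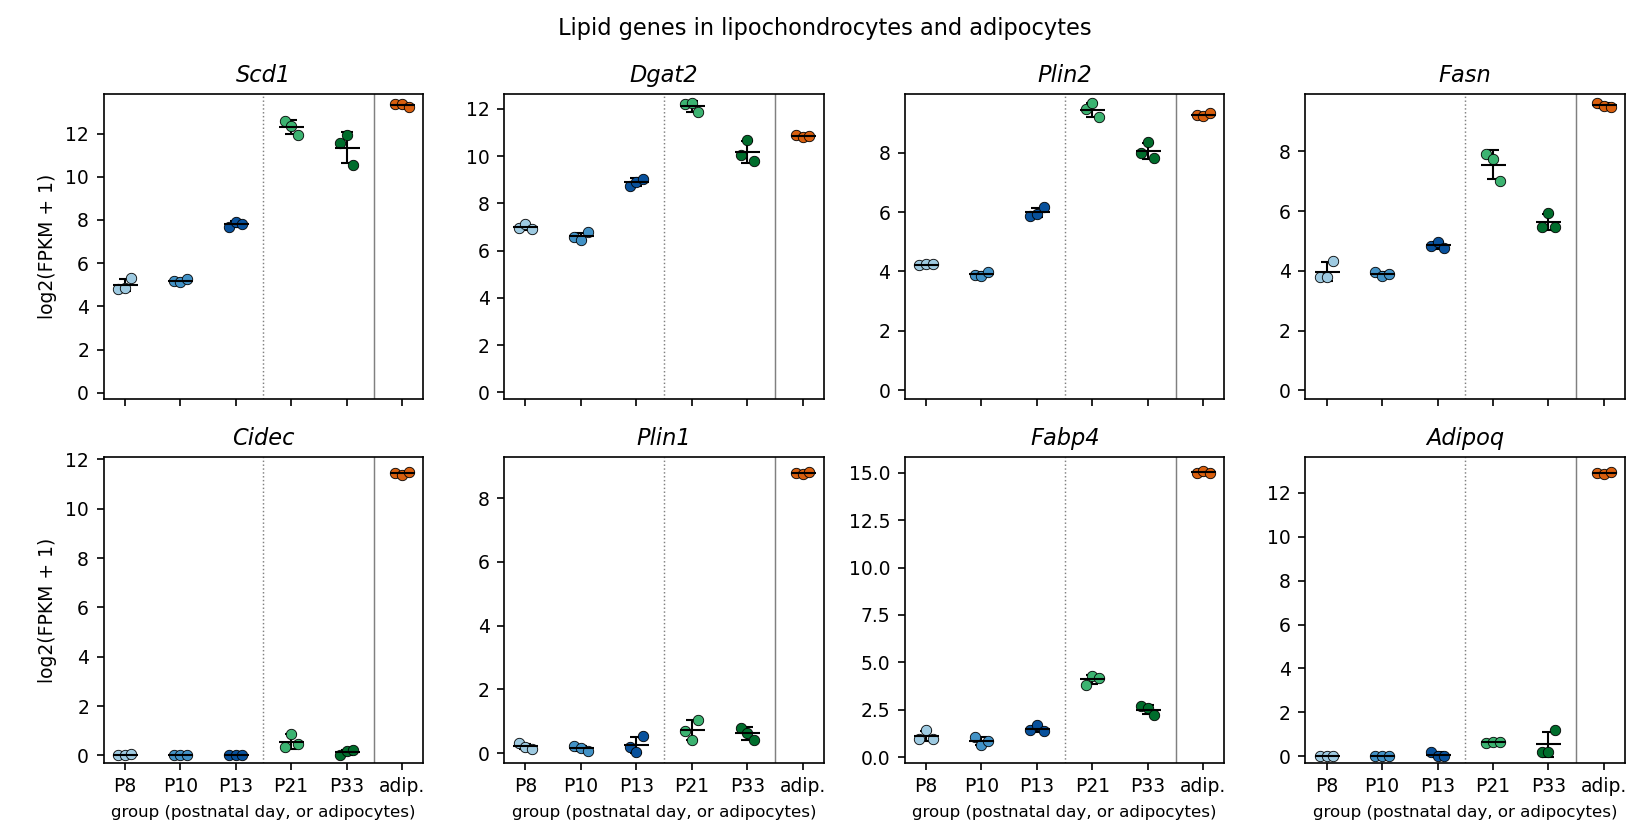
Log2(FPKM + 1) of Scd1, Dgat2, Plin2, Fasn, Cidec, Plin1, Fabp4 and Adipoq by group, with 1 point per library and bars for mean ± SD; the dotted line separates sorted from buoyant stages and the solid line separates the adipocytes. Scd1 runs from 31.1 FPKM at P8 to 5110 at P21, 2800 at P33 and 10200 in adipocytes, whereas Adipoq stays under 1 FPKM in the lipochondrocyte group means.

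Angptl7 (ENSMUSG00000028989.3, chromosome 4:148495183 to 148500460) showed the largest rise from P13 to P21, from 2.6 ± 0.24 to 1020 ± 580 FPKM (7.94, SE 0.35, adjusted p = 4.04e-10). Cilp2 rose by 7.04 (SE 0.39, adjusted p = 4.50e-09), Comp by 6.84 (SE 0.36, adjusted p = 3.05e-09), Wfdc2 by 6.67 and Chad by 4.67, the last from 118 ± 51 to 3090 ± 1300 FPKM. Spp1 rose by 4.53 to 316 ± 170. Col2a1 fell by 2.19 (SE 0.17, adjusted p = 1.60e-07) to 929 ± 76 FPKM and Eln by 1.02 (SE 0.25, adjusted p = 4.38e-03) to 12000 ± 2100. Acan was not called (0.62, adjusted p = 2.20e-01) except with sample weights (0.64, adjusted p = 3.88e-02), and Sox9 was not called at -0.20 (adjusted p = 5.03e-01) but was called at -0.65 under median-of-ratios scaling (adjusted p = 1.83e-02). Fos (ENSMUSG00000021250.13, chromosome 12:85473890 to 85477273) changed by -9.63 (SE 0.41, adjusted p = 2.53e-10), Atf3 by -8.08, Junb by -8.05, Zfp36 by -7.75 and Egr1 by -6.84.

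**Figure D3:**
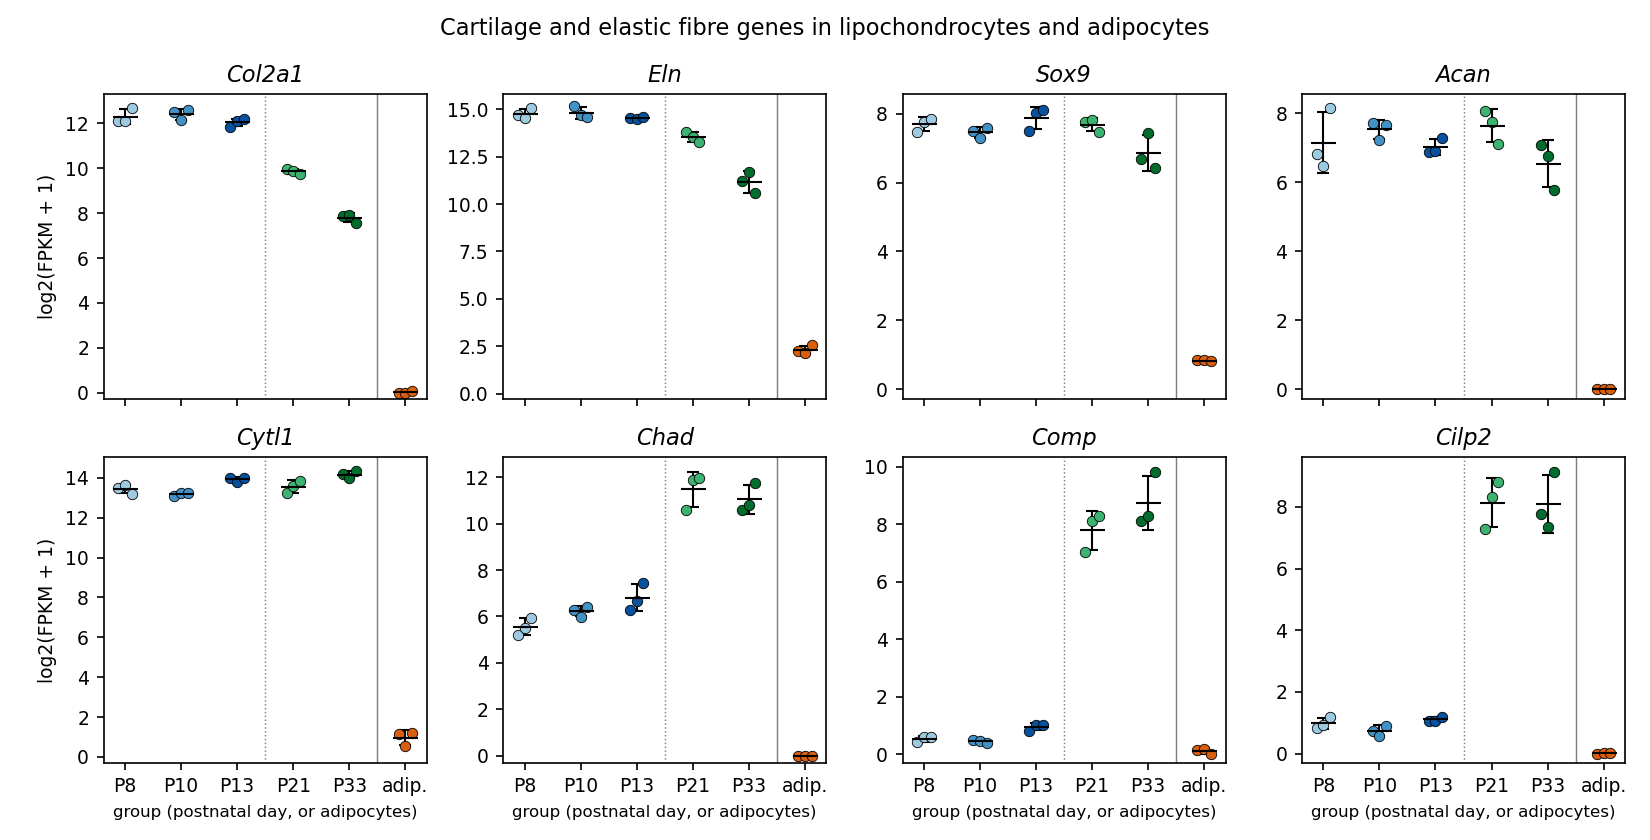
Log2(FPKM + 1) of Col2a1, Eln, Sox9, Acan, Cytl1, Chad, Comp and Cilp2 by group, drawn as points for libraries and bars for mean ± SD, with the dotted line between sorted and buoyant stages and the solid line before the adipocytes. Col2a1 falls from 5100 FPKM at P8 to 223 at P33 while Comp rises from 0.447 to 499.

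In total 5949 genes changed from P13 to P21, with 4977 rises and 972 falls. The all-gene median was 0.289, and 0.006 under median-of-ratios scaling, where 2212 genes rose and 2214 fell. Rescaling each library to the same sum gave 3189 rises and 1314 falls, and quantile normalization gave 2114 and 2312. Relative to that shift, fewer list members rose, so each count below is followed by its value under median-of-ratios scaling; each list call below was lost with an estimated correlation unless stated. Of 17 fatty acid synthesis genes, 15 rose and 0 fell, or 10 and 1 after scaling (list test adjusted p = 3.31e-05, but adjusted p = 0.32 with an estimated correlation). Triglyceride synthesis had 10 rises of 14, or 11 adjusted over the list alone and 9 after scaling (9.76e-04, and 0.265 with an estimated correlation), with Gpd1 and Agpat2 beside Dgat2. Droplet coat had 11 rises of 12, or 6 after scaling (0.00119, and 0.0796), and lipolysis 9 rises and 1 fall of 12, or 8 and 1 (0.0251, and 0.265). Adipocyte identity genes had 11 rises of 16, or 7 after scaling (0.0126, and 0.276), led by Rbp4, Slc2a4 and Car3, the last reaching 4.49 ± 0.45 FPKM. Uptake (10 rises and 4 falls, or 5 and 5 after scaling, adjusted p = 0.489), oxidation (13 rises, or 3 rises and 2 falls, 0.0742), oxidative phosphorylation (8 rises, or 5 falls), cholesterol synthesis (8 rises, or 3 rises and 5 falls, 0.828), glycolysis (9 rises and 3 falls, or 6 and 5) and brown fat genes (5 rises, and 5 after scaling, 0.264) were not called as lists, except brown fat after scaling (0.044).

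Cartilage matrix split into 7 rises, among them Cilp2, Comp, Chad and Ucma, and 9 falls, among them Col2a1, Col11a1 and Epyc, or 6 and 11 after scaling (adjusted p = 0.06; median -0.37 but mean 0.80). Elastic fibre genes split into 4 rises, with Mfap4 and Fbn1, and 6 falls, with Fbn2 and Eln, or 2 and 8 after scaling and 6 of each over the list alone (0.0203, and 0.336 with an estimated correlation; median -0.17 but mean 0.06); this list call was also lost under median-of-ratios scaling (0.0845). Collagen processing had 3 rises and 6 falls, led by Serpinh1 among the falls, or 2 and 13 after scaling (3.57e-04, and 0.276). Transcription factors had 2 rises and 2 falls, or 1 and 3 after scaling, with Trps1 up and Sox6 down, the latter lost without P13 replicate 1 (6.08e-02). Hypertrophy genes had 3 rises and 1 fall, or 1 of each after scaling. All 22 proliferation genes fell before and after scaling, led by Cdk1 (-2.72), Ccna2 and Birc5, and this call held with an estimated correlation (2.30e-31, and 1.96e-04). So did the dissociation response, with 15 falls of 16 in either case (1.87e-43, and 4.44e-04). Markers of other cells rose beside the lipid genes. Macrophage genes had 8 rises of 12, or 7 after scaling, with Lyz2 going from 1.8 ± 0.06 to 10.6 ± 2.7 FPKM (0.0126, and 0.276). Skeletal muscle had 7 rises of 8, and 7 after scaling, with Acta1 from 18.6 ± 6.7 to 162 ± 120 (0.0493, and 0.626), and erythroid genes 4 of 5, and 4 after scaling, with Hba-a2 from 3.09 ± 0.63 to 160 ± 130 (0.0126, and 0.32). Fibroblast genes had 9 rises and 2 falls, led by Ly6a, Dcn and Col1a1, or 8 and 4 after scaling (0.179). The endothelial list had 0 rises, and Tek was its single fall, lost after scaling.

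From P21 to P33, both buoyant, 14 of 17 fatty acid synthesis genes and 16 of 20 cholesterol synthesis genes fell, though neither list call held with an estimated correlation (adjusted p = 0.0828 for each). The matrix genes Lox, Eln, Col2a1 and Col9a2 fell as well. Dgat2 fell to 1190 ± 390 FPKM, Plin2 to 269 ± 53, Fasn from 194 ± 60 to 49.4 ± 9.9 and Mogat1 from 49.3 ± 15 to 8.12 ± 3.6. The elastin cross-linking gene Lox fell from 529 ± 160 to 69.6 ± 22, and Eln from 12000 ± 2100 to 2400 ± 900. Grem1, Myoc and Gsn rose, with Gsn going from 2620 ± 530 to 10400 ± 1300 FPKM. The falls were -1.94 for Dgat2 (SE 0.19, adjusted p = 1.20e-05), -1.38 for Plin2 (SE 0.14, adjusted p = 1.48e-05), -1.92 for Fasn (SE 0.21, adjusted p = 3.57e-05), -2.07 for Acly (adjusted p = 2.16e-04) and -2.50 for Mogat1 (adjusted p = 8.75e-05). Scd1 fell by 0.95 (SE 0.27, adjusted p = 3.45e-02), a call lost without P21 replicate 1, P21 replicate 2 or P33 replicate 3 (adjusted p from 6.64e-02 to 1.15e-01). Lox fell by 2.92 (SE 0.24, adjusted p = 2.80e-06), Eln by 2.38 (SE 0.25, adjusted p = 2.50e-05), Col2a1 by 2.06 (SE 0.17, adjusted p = 2.96e-06) and Col9a2 by 2.61 (adjusted p = 3.17e-05). Aacs, Timp1, Nid2 and Pdzk1ip1 were the other genes among the 6 largest falls, with Aacs going from 371 ± 67 to 52.3 ± 15 FPKM. Grem1 rose from 2.41 ± 0.29 to 32.1 ± 7.7 FPKM (3.26, SE 0.16, adjusted p = 2.23e-08), Myoc from 166 ± 77 to 1400 ± 220 (3.16, adjusted p = 1.75e-06), and Gpx3, Thbs4 and Tmem213 by 2.60, 2.38 and 2.29. Acan (-1.10, adjusted p = 9.49e-02) was not called, except with sample weights (-0.91, adjusted p = 2.06e-02).

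The P21 to P33 comparison had 1388 genes called, with 397 rises and 991 falls, 258 rises and 1320 falls after rescaling each library to the same sum, and 262 rises and 849 falls with a pseudocount of 0.1. Without P21 replicate 2 the count was 906 (241 rises, 665 falls), without P33 replicate 3 it was 1802 (659 rises, 1143 falls), and with only these 2 groups in the model it was 126. Of the genes given with a change or FPKM in these P33 and P21 paragraphs, Lox, Col2a1, Aacs, Grem1, Myoc, Tmem213 and Gsn were still called with only these 2 groups, whereas Dgat2, Plin2, Fasn, Scd1, Acly, Mogat1, Eln, Col9a2, Gpx3, Thbs4, C1qb, Lyz2 and Fos were not. Of the list members named without values, Idi1, Cd36, Slc2a4, Dcn, Postn, Lum, Tnnt3 and Hbb-bt also lost their calls there. P33 replicate 3 stood apart from the other P33 libraries on the third component. Fatty acid synthesis had 14 falls of 17, or 16 adjusted over the list alone (list test adjusted p = 2.45e-16, but adjusted p = 0.0828 with an estimated correlation). Cholesterol synthesis had 16 falls of 20, or 17 over the list alone, led by Fdps, Idi1 and Pmvk (2.58e-15, and 0.0828 with an estimated correlation). Triglyceride synthesis had 6 falls of 14 (0.00116, and 0.171), droplet coat 3 of 12, or 4 over the list alone (0.014, and 0.144), uptake 7 of 15, led by Cd36 (0.00804, and 0.132), and oxidation 5 of 17, or 6 (0.00116, and 0.171). Adipocyte identity had 4 falls of 16, or 9 over the list alone, with Slc2a4 down (0.00128, and 0.14). Elastic fibre had 7 falls of 16, or 9 (3.61e-06, and 0.0907), and collagen processing 6 of 18, or 11 falls and 1 rise, with P4hb down (2.23e-04, and 0.191). Cartilage matrix had 8 falls and 2 rises, which were Cilp and Fmod, or 10 and 4 over the list alone (0.00576, and 0.144). Glycolysis had 4 falls of 20, or 7 falls and 1 rise (0.0466, and 0.3 with an estimated correlation), a list call also lost under median-of-ratios scaling (0.059). Lipolysis (1 rise and 2 falls, 0.739) and proliferation (0 called of 22, 0.739) were not called.

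Markers of other cells moved in both directions from P21 to P33. Macrophage genes had 6 rises of 12, among them C1qb from 4.77 ± 1.3 to 11.8 ± 4.8 FPKM and Lyz2 from 10.6 ± 2.7 to 24 ± 8.2 (list test adjusted p = 5.23e-05, but adjusted p = 0.0828 with an estimated correlation). The skeletal muscle list moved down with Tnnt3 alone called, a call lost without P21 replicate 1, P21 replicate 3 or P33 replicate 1, or 6 of 8 genes adjusted over the list alone (0.0101, and 0.512 with an estimated correlation), and the erythroid list with Hbb-bt called, or 4 of 5 over the list alone (0.014, and 0.293). The dissociation response had 4 falls of 16, or 8 over the list alone, with Fos from 16.7 ± 17 to 1.7 ± 0.49 FPKM (0.00116, and 0.293). Fibroblast genes had 3 rises, with Dcn and Dpt, and 4 falls, with Postn and Lum, or 4 of each over the list alone (0.885). No list of this comparison held with an estimated correlation.

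Over the whole span from P8 to P33, all 22 proliferation genes fell and 9 of 12 droplet coat genes rose, or 6 after median-of-ratios scaling. The proliferation list held with an estimated correlation (list test adjusted p = 1.97e-23, and 8.48e-04), as did the dissociation response with 15 of 16 genes lower, or 16 adjusted over the list alone (5.16e-29, and 0.00286). Cdk1 went from 24.6 ± 1.9 to 0.89 ± 0.35 FPKM. Droplet coat genes had 9 rises of 12, or 10 over the list alone (0.00332, but adjusted p = 0.1 with an estimated correlation), triglyceride synthesis 10 rises of 14 (0.00518, and 0.303) and lipolysis 9 rises and 1 fall of 12 (0.0297, and 0.175). Macrophage genes had 10 rises of 12, or 11 over the list alone (3.80e-04, and 0.1). Single genes of other markers rose as well: 6 of 8 skeletal muscle genes (6 after scaling) and 4 of 5 erythroid genes (4 after scaling). Fibroblast genes had 8 rises and 3 falls of 14, or 7 and 4 after scaling. Elastic fibre genes had 10 falls and 2 rises (1.07e-05, and 0.1), collagen processing 11 falls and 2 rises, or 12 falls over the list alone (2.51e-06, and 0.143), and cholesterol synthesis 10 falls and 3 rises (3.28e-04, and 0.446). Cartilage matrix was split at 9 of each (0.259), and fatty acid synthesis at 9 rises and 2 falls was not called (0.165). Of all genes, 6660 changed, with 4898 rises and 1762 falls; the all-gene median moved from 0.234 to 0.025 under median-of-ratios scaling, where 3189 rose and 2963 fell. Rescaling each library to the same sum gave 2966 rises and 2823 falls, and quantile normalization 3044 and 3279. After median-of-ratios scaling, triglyceride synthesis had 7 rises, lipolysis 8 rises and 1 fall, macrophage genes 9 rises, elastic fibre 10 falls and 2 rises, collagen processing 14 falls and 2 rises, cholesterol synthesis 12 falls and 1 rise, cartilage matrix 7 rises and 10 falls, fatty acid synthesis 7 rises and 3 falls, and the dissociation response 16 falls, while all 22 proliferation genes fell. The isolation differed between these stages too.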

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

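The search for opposite courses, the tests for adipocyte carry-over and for the change of isolation, and both tests of sorting were chosen after the results were seen. Leaving out the 20 most abundant genes was chosen after more rises than falls were seen, with its bounds, like those of the scaling tests, written before its own result.

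Dgat2, Scd1 and Mogat1 rose early and fell late, and they belong to a set of 158 genes. These were called in opposite directions from P8 to P13 and from P21 to P33, with the difference between the changes also called in the same model. The called difference is no separate support, because a gene called in opposite directions in both comparisons was bound to pass it. Of the 158 genes, 147 rose first and fell later, and 11 did the reverse. Spp1 rose by 2.49 and changed by -2.05 later (difference -4.55, SE 0.54, adjusted p = 7.01e-05), Mogat1 by 1.81 and -2.50 (-4.31, SE 0.43, 1.40e-05), Dgat2 by 1.89 and -1.94 (-3.84, SE 0.26, 5.04e-07) and Scd1 by 2.81 and -0.95 (-3.77, SE 0.38, 1.53e-05). Sfrp2 went the other way, from -1.92 to 1.29. With only P21 and P33 modelled, the late falls of Spp1, Mogat1, Dgat2 and Scd1 were not called (adjusted p = 1.85e-01, 6.73e-02, 5.99e-02 and 3.44e-01). That model called 98 falls in all, fewer than 147, and opposite courses were not counted with it. Without P8 replicate 1 the count of opposite courses was 99, and without P13 replicate 3 it was 90. The 11 that fell first became 34 without P33 replicate 3, 7 without P13 replicate 1, 6 without P8 replicate 3, P21 replicate 2 or P33 replicate 1, 5 without P13 replicate 3 and 51 with sample weights. They were 17 under quantile normalization and 6 with no filter. Of 100 splits of the libraries within the early and within the late stages, 1, the real one, gave as many genes, and the highest other gave 29. That test is void for opposite courses, because no other split of the P8 and P13 libraries called more than 3 genes, so most of the 100 splits were bound to give fewer than 158. For scale, 147 of the 371 early rises fell later, while 991 of all 13815 genes fell. Of the 210 early falls, 11 rose later, while 397 of all genes rose. Both shares were above those over all genes, but genes are not independent of each other and no valid test was run. Whether the courses oppose each other more often than by chance is therefore left open. The early pair was sorted and the late pair buoyant, so age and isolation differ together between the pairs, and no explanation of the difference was tested.

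Of the fatty acid synthesis, triglyceride synthesis and droplet coat lists, 36 members were higher at P21 than at P13. Adipocytes carried over into the buoyant fraction are a candidate source, but the tables argue against them for the members as a set: the 16 adipocyte identity genes stood at a median of 0.058% of the adipocyte level at P21, a share that would supply 0.42% of the rise of the median member, and Cfd (0.00354%), Adipoq (0.00732%), Car3 (0.0157%) and Retn (0.0189%) lay lower still. That test speaks to the median of the 36 members; its bound was narrowed to the median share after the upper quartile (4.64%, set by genes such as Rbp4 at 19.4%) was seen to supply 33.58%, which under the wider bound had left it open. For 3 members (Acsl1, Plin1 and Cidec) the median share would supply at least 10%, and these stay open. Scaling stays open for part, since 25 members were still called after median-of-ratios scaling and 11 were not. That scaling lowered changes by about the all-gene shift. The change of isolation stays open too: 8 members were also higher at P13 than at P8 under 1 isolation. The median change over the 36 was 0.34 there, against 1.02 from P13 to P21. The 36 were picked for their rise from P13 to P21, and P13 enters both changes with opposite sign. A smaller early change was thus favoured in advance and decides nothing, so age and isolation cannot be told apart.

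Immediate early genes were lower at P21 and P33 than in sorted cells. Sorting alone may raise such genes, but the adipocytes, which were not sorted, lay above P33 by a median of 5.50, so a high level did not need sorting; this compares 2 tissues and leaves the fall from P13 to P21 open. Between P21 and P33, under 1 isolation, the median change was -0.41, too small to separate age from sorting for the step before. Scaling is argued against, since the median change was -6.57 after median-of-ratios scaling. Age and the change of isolation stay open as causes of that step.

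More genes rose than fell from P13 to P21 (83.7% of calls). A few abundant genes are argued against as the whole cause, since rises were 77.4% of calls without the 20 most abundant. That setting also rescaled each library to the same sum. With those genes kept, rescaling gave 70.8% rises and an all-gene median of 0.145, against 0.239 without them and 0.289 as reported. Under the same rescaling, leaving these genes out therefore did not lower the share of rises. Under median-of-ratios scaling rises were 50%, which met the bound written before for scaling as a cause, but that test is void because such scaling centres the median change and so fixes the share near this value. Library scaling and a real shift in RNA composition cannot be told apart without an external standard, and a biological shift with age stays untested.

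The 6 libraries of a comparison can be split in 10 ways, the real one included, too few for a share under 0.05. In each comparison the real split alone (1 of the 10) gave as many genes as reported. The real count and the highest other were 9466 and 1 for P33 with adipocytes, 9331 and 2 for P21, 9924 and 2 for P13, 10463 and 2 for P10 and 9879 and 1 for P8. Among stages they were 1525 and 68 for P10 with P8, 3124 and 1 for P13 with P10, 581 and 3 for P13 with P8, 5949 and 1 for P21 with P13, 1388 and 559 for P33 with P21, and 6660 and 8 for P33 with P8.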

How the results depend on the processing

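Of the results here, the count of opposite courses and the count without the 20 most abundant genes (5107 for P21 with P13) were chosen after seeing the data. No named gene or list reversed its call. Among all calls against adipocytes, median-of-ratios scaling reversed 115 at P13, 375 at P10 and 53 at P8, and quantile normalization reversed 247, 508 and 192, with 2 at P21 and 5 at P33; both scalings shift the all-gene median, which was furthest from 0 at these stages. For P10 with P8 median-of-ratios scaling turned 262 higher and 1263 lower into 497 and 125, and for P21 with P13 it gave 5 falls and 0 rises of oxidative phosphorylation genes in place of 8 rises and 0 falls, with 0 calls of that comparison reversed. Total counts of changed genes stayed within 1.5 times the reported count for a pseudocount of 0.1, rescaling to the same sum and the replicate block. Rises or falls alone did not: rescaling gave 2966 rises and 2823 falls for P33 with P8 (4898 and 1762 reported), 3189 rises for P21 with P13 (4977) and 258 for P33 with P21 (397), and a pseudocount of 0.1 gave 262 for the last. Causes were not tested unless stated.

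For P10 with P8 (1525 genes) the count was 985 with no filter, 622 after median-of-ratios scaling and 524 after quantile normalization; the cause was not tested. A minimum of 5 FPKM left 8245 genes to test, so fewer were called: 6189 at P33, 6150 at P21, 6552 at P13, 6837 at P10 and 6547 at P8 against adipocytes. With only the 2 groups modelled, which leaves 6 libraries for the spread, 351 genes were called for P10 with P8, 347 for P13 with P8 and 126 for P33 with P21. The same restriction gave 8971 for P33 and 9573 for P21 with adipocytes. The reported model shares the spread of a gene over all groups, yet the groups differed in spread. Correlations between libraries of a group were 0.924 to 0.971 at P33 and 0.977 to 0.980 in adipocytes. Whether fewer libraries or unequal spread lowered the counts was not tested. Sample weights gave 3323 for P10 with P8, 4764 for P13 with P10, 1071 for P13 with P8, 3170 for P33 with P21 and 351 opposite courses. A minimum of 2-fold, which can only remove genes, left 5491, 5325, 6182 and 6265 at P33, P21, P13 and P8 against adipocytes, 188 for P10 with P8, 513 for P13 with P10, 195 for P13 with P8, 1805 for P21 with P13, 344 for P33 with P21 and 2466 for P33 with P8.

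Leaving out 1 library at a time gave 8842 to 9549 genes for P33 with adipocytes, 8721 to 8959 for P21, 9407 to 9602 for P13, 10002 to 10181 for P10, 9334 to 9828 for P8, 520 to 1493 for P10 with P8, 1938 to 2830 for P13 with P10, 339 to 509 for P13 with P8, 4898 to 5366 for P21 with P13, 906 to 1802 for P33 with P21, 5834 to 6627 for P33 with P8 and 90 to 213 opposite courses. Counts moved by over 1.5 times without P8 replicate 1 (381 for P13 with P8, 99 opposite courses), P13 replicate 3 (339 and 90), P8 replicate 2 (640 for P10 with P8), P8 replicate 3 (914), P10 replicate 1 (520, and 1938 for P13 with P10), P10 replicate 2 (794) and P21 replicate 2 (906 for P33 with P21).

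Of 120 list results, 49 lost their call with an estimated correlation, and most of the other 71 were not called in either setting. The calls that held for P33 with adipocytes were cartilage matrix, adipocyte identity, fatty acid oxidation, droplet coat, lipolysis, uptake, endothelium and macrophage. For P21 with P13 they were proliferation and the dissociation response, and none held in the other main comparisons. For named genes, 68 calls were lost with only 2 groups modelled, 19 were lost and 3 gained under median-of-ratios scaling, and 115 were lost and 5 gained over 2100 results without 1 library. A block for the replicate number called 9571 genes for P33 with adipocytes, 661 for P13 with P8, 6105 for P21 with P13, 1546 for P33 with P21 and 170 opposite courses. Whether the numbers pair the libraries is left open. Of 18 libraries, 8 correlated best with their own number. The 45 same-number pairs had residual correlations of -0.17 to 0.31, with 13 over 0.1, against -0.34 to 0.31 for pairs of different number. The block called more genes than reported in each of these comparisons, so some structure shared by number is not excluded. FPKM give no counts per gene, so the depth behind a low value is unknown.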

Other observations

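The values here were picked after they were seen, and no explanation was tested for them.

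The gene 1520401A03Rik, protein coding on chromosome 17:23704488 to 23722783, was abundant at the early stages and lower at each later stage. It stood at 94700 ± 7400 FPKM at P8, 92300 ± 4500 at P10, 96500 ± 13000 at P13, 16700 ± 3600 at P21 and 478 ± 240 at P33, against 0.0833 ± 0.04 in adipocytes (SD, n = 3). Apoe rose through the stages, from 375 ± 18 FPKM at P8 to 836 ± 170 at P10, 1440 ± 200 at P13, 12800 ± 3700 at P21 and 18300 ± 3900 at P33, which is above the 6120 ± 320 of adipocytes. Sparc went from 34100 ± 6400 at P8 to 164000 ± 34000 at P33, against 2620 ± 150 in adipocytes. Gsn went from 88.3 ± 9.1 at P8 to 10400 ± 1300 at P33, against 6560 ± 88 in adipocytes. Ucma was at 34.5 ± 2.8 FPKM at P13 and 941 ± 380 at P21.

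Rps3a2 and Rps3a3, processed pseudogenes in GENCODE M21, were near 0 in all P13 and adipocyte libraries and in P33 replicate 2, while Rps3a1 was not. Rps3a2 was at 701 ± 3 FPKM at P8 and 676 ± 80 at P10, 0.487 ± 0.84 at P13, 261 ± 86 at P21 and 263 ± 230 at P33, and was listed at 0 in adipocytes. Rps3a3 was at 479 ± 12, 499 ± 34, 0.72 ± 0.26, 162 ± 71, 211 ± 180 and 0.187 ± 0.19 FPKM in the same order. Rps3a1 was at 1550 ± 80, 1220 ± 85, 1830 ± 150, 909 ± 300, 879 ± 280 and 198 ± 6.5 FPKM. At P33 Rps3a2 ran from 1.15 to 398 FPKM and Rps3a3 from 1.2 to 332, with replicate 2 the lowest for both, so these P33 means mix unlike libraries. How reads were divided among these genes is not given in the sources used here. These steps lie between the groups of the P13 with P8 and P21 with P13 comparisons and within P33. The groups may therefore differ in more than age and isolation, which was not tested.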
